A study of Bos taurus with 6 samples.

How the data were processed

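Granulosa cells, the layer of follicle cells that surrounds the oocyte and makes oestradiol, were taken from the dominant follicle of Hereford cows on day 3 of the first follicular wave. Per the labels, 6 cows were used as 3 pairs, each of 1 aged and 1 young cow. The 2 RNA samples of a pair were hybridised together on 2 arrays with the dyes exchanged, which gives 6 arrays. The labels' protocols state that RNA was isolated with a column kit, amplified, and linked to Cy3 or Cy5 without an enzyme step. They also state that cells were collected by ovary removal or by aspiration, and were frozen or kept in RNAlater, without saying which cow had which. The aged cows are labelled multiparous and the young cows heifers, so age and parity cannot be told apart.

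The values used are mean spot intensity and median local background intensity in each channel, as the authors deposited them in the scanner output, per the file headers without background subtraction or normalization. The scanner and image software are not given in the sources used here. The authors also deposited a processed table of log2 ratios, which was used as an alternative. Its columns follow Cy5 over Cy3 on every array, since each correlated with the raw ratio of its own array with r from 0.583 to 0.791, and its column medians lay between -0.0115 and -0.00133. Its rows carry the same probe names as the scanner output. How that table was scaled and centred is not given in the sources used here. The submitters' processing notes name limma, with no version. Another deposited processed table was not used, because its 6 columns of per-sample values carry names that match no label.

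Each array held 45220 spots, of which 43794 were probes and 1426 were controls or blanks, including 153 negative control spots. Background was corrected by normexp with an offset of 50, and log2 ratios were normalized within each array by loess, with control spots and spots marked as ignored at weight 0. A probe was kept when it lay above the mean plus 2 SD of the negative control spots in at least 1 channel on at least 3 arrays, which left 23122 probes. In the platform annotation, 21790 probes had 1 gene symbol, 0 had several and 22004 were unnamed here. Of the 15229 symbols, 15096 were found in NCBI RefSeq's gene table for assembly ARS-UCD2.0 as a current symbol or a synonym, 982 were updated through a synonym, and 133 kept the platform's name. That table served for names alone. A gene with several kept probes was represented by the brightest, and 9683 genes were tested. In 2062 genes with more than 1 kept probe, the log2 ratios of the 2 brightest probes correlated across genes with r = 0.473.

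Ratios were turned to aged over young, and the 2 arrays of a pair were averaged, so that n = 3 pairs. A dye effect that is the same on both slides cancels in that mean. A dye effect that differs between slides does not cancel and would enter all 3 pairs alike. The 3 arrays with the aged cow in Cy5 lie on one slide and the 3 with the young cow in Cy5 on another. limma 3.58.1 in R 4.3.3 tested each gene's mean log2 ratio against 0, two-sided, with empirical Bayes variances and Benjamini-Hochberg adjustment. In total 29 gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the lists, and again with a correlation estimated per list. The pairing comes from co-hybridisation and the cows of a pair are different animals. The number of arrays limits the precision of each value.

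The design, lists, named-gene rule and alternative settings were fixed before the data were examined. The rule named the 10 genes with the highest and the 10 with the lowest log2 ratio among those past an adjusted p of 0.05 with the same sign on all 6 arrays. Where fewer passed, places were filled from genes with an unadjusted p under 0.05 and the same sign on 6 arrays, by p. It also named a fixed set of granulosa cell genes, and up to 4 members with the smallest p of each list past the threshold and of each list given a count. Besides the called lists, 9 lists were given counts, and these 9 were chosen after their values were seen. A probe that was not above the negative controls in the channel of one cow on either array of a pair has only a bound there, given as "at least", from means of log2 intensities after loess and Aquantile. The same holds for a pair in which the brighter cow's signal lay near the maximum on both arrays, that is, over 0.8 of the brightest probe of its channel, as 49 to 200 probes did per array and channel. Means over pairs keep the measured ratio of such a pair. No bound is taken from a signal near the maximum if the other cow's signal was also near the maximum, or not above the negative controls, on an array of that pair.

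The fit was tested on simulated data with 3 pairs and 9683 independent genes, each with its SD over the real pairs as its true spread. At the adjusted threshold it recovered 28% of genes changed 2-fold, 60% of those changed 4-fold, 68% of those changed 8-fold and 70% of those changed 16-fold. Genes that move together within a pair were not simulated there. Each SD came from 3 values, so the simulated spreads vary more between genes than true spreads would. These shares thus need not hold for the real data. In 50 draws of simulated data with no age effect, camera with the preset correlation called the cell cycle list in 0% of draws with independent genes. It called that list in 54% of draws in which its members moved together within a pair by as much as in the real pairs. Alternatives covered background correction, normalization, the filter on dim probes, the authors' processed values, the probe chosen for a gene, the treatment of technical replicates, each slide alone, unpaired cows, the variance prior and leaving out each pair. After the data were seen, 3 more were added, a filter from the median and MAD of the negative controls, a fit without the array with the brightest negative controls and a fit without probes near the maximum.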

Results

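The measurements are 2-colour array signals from granulosa cells of 3 aged and 3 young cows, set against each other in 3 pairs with 2 dye-swapped arrays each. Median raw signals lay between 158 and 356 in Cy5 and between 165 and 445 in Cy3. On 5 of the arrays 30.3% to 66.9% of probes lay above the negative controls in Cy3. On the remaining array, that of pair 2 with the young cow in Cy5, the share was 9.79%, because some negative control spots there reached 7474. The study asked how maternal age changes the transcripts of these cells when the dominant follicle is selected.

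CRISPLD2, which encodes a secreted protein, had a mean log2 ratio of aged over young of -1.44 ± 0.15 (SD, n = 3 pairs), with -1.45, -1.59 and -1.28 in the 3 pairs. It was the only gene at least 2-fold different in the same direction on all 6 arrays. RPL36, a protein of the large ribosomal subunit, had a mean log2 ratio of 0.94, which is no bound. Its signals lay near the maximum on 6 of 6 arrays in aged cows and on 3 in young cows. Its log2 ratios were 1.77, 1.66 and 1.60 on the arrays with the aged cow in Cy5 but 0.06, 0.19 and 0.37 in the other orientation, and such signals limit both their size and their spread. MYL9, a myosin light chain of smooth muscle, had 0.96 ± 0.24. Of 9683 genes, limma placed 0 past an adjusted p of 0.05, with a smallest adjusted p of 0.793. At an unadjusted p under 0.05, 484.2 genes would be expected by chance, with a wider spread where genes move together. There were 597 genes, 267 of them with higher and 330 with lower values in aged cows. Of these, 29 also differed at least 2-fold, 8 with higher and 21 with lower values in aged cows. With dye and slide as a term and the pair as a block, limma called 0 genes past the adjusted p and 908 at an unadjusted p under 0.05. On the slides with the aged and the young cow in Cy5 alone it called 0 and 0, with 533 and 1261 at an unadjusted p under 0.05. In median-centred ratios the split at unadjusted p became 340 higher and 226 lower, and with a 2-fold change 22 and 17. That 2-fold split was 88 higher and 15 lower without pair 1, and 127 and 65 on the slide with the young cow in Cy5.

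The genes named next had the same direction on all 6 arrays and did not pass. HNRNPM, a splicing factor, had a log2 ratio of -0.99 ± 0.13 (SD, n = 3 pairs), TFDP1, a partner of E2F transcription factors, -0.91 ± 0.13, and TP53BP2, which binds p53, -1.01 ± 0.17. HAT1, a histone acetyltransferase, was at -0.77 ± 0.10, H2AZ1, a histone variant, at -0.80 ± 0.15, and RBM8A, of the exon junction complex, at -0.78 ± 0.13. CENPK, a kinetochore protein, was at least 1.59-fold lower in pair 1 and at -0.67 in pairs 2 and 3. ARHGEF3 stood at -0.93 ± 0.15 and RAD50, of the double-strand break repair complex, at -0.71 ± 0.12. Among those with higher values, CDKAL1 had 0.87 ± 0.17, POLR1D 0.87 ± 0.23, DHX58 0.81 ± 0.17, FUCA1 0.73 ± 0.13, NDUFS5 0.72 ± 0.17, COPS2 0.64 ± 0.12 and BLVRB 0.57 ± 0.04. ADSS1 was at least 1.50-fold higher in pair 1. BLVRB read 0.09, 0.05 and 0.24 with the aged cow in Cy5 and 1.01, 1.02 and 0.98 with the young cow in Cy5. Signals of the aged cows were above the negative controls on 3 of 6 arrays for CENPK, 4 of 6 for ARHGEF3 and ADSS1, and 5 of 6 for HNRNPM, TFDP1, HAT1, RBM8A, RAD50 and DHX58. Each of these genes missed 1 array in pair 2, and those at 5 of 6 missed no other. There the threshold of the aged cow was 1572 on 1 array, raised by bright negative control spots, against 284 on the other. These counts thus do not by themselves mean a dim signal. Probes of one gene did not always go together. The other 2 probes of CRISPLD2, both dimmer, had -0.30 and 0.04, the 3 dimmer probes of HNRNPM had -0.07, -0.18 and -0.08, and the other probe of POLR1D had -0.14. The second probe of RPL36 had 0.87, that of RBM8A -0.63 and that of COPS2 0.31. Of genes named below, the other probes had -0.26 for STAR, -0.46 for SOD1, -0.54 and -0.98 for PDIA6, and 0.03, -0.74 and -1.12 for MSMO1.

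**Figure D1:**
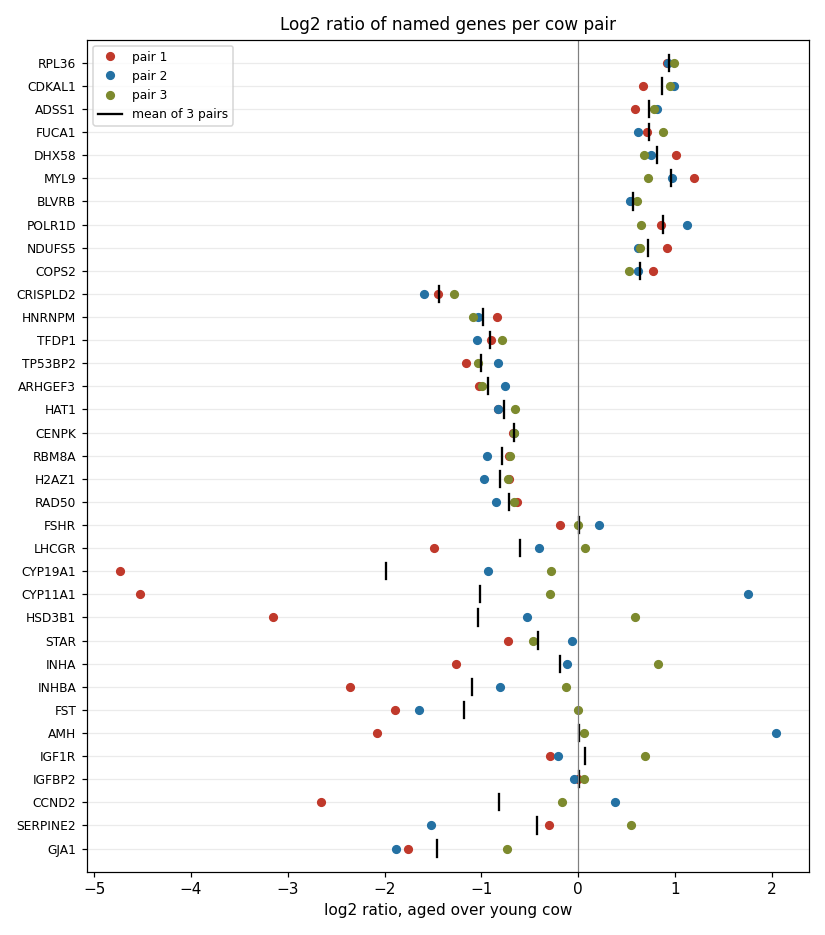
Log2 ratio of aged over young cow (x axis) for the genes named by rule or fixed in advance (y axis), 1 point per cow pair and a black bar at the mean of 3 pairs. The points of CRISPLD2 lie between -1.59 and -1.28, while those of CYP11A1 lie between -4.52 and 1.75.

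Of the genes of oestradiol synthesis and follicle growth none passed. CYP19A1, the aromatase, had log2 ratios of -4.74, -0.93 and -0.28 in pairs 1 to 3 (mean -1.98 ± 2.41, SD, n = 3 pairs), and its other probes had means of -0.78 and -1.09. CYP11A1, which makes pregnenolone from cholesterol, had -4.52, 1.75 and -0.29, and HSD3B1, which makes progesterone, -3.15, -0.53 and 0.59. AMH, anti-Müllerian hormone, had -2.08, 2.04 and 0.06, and CCND2, a cyclin that drives granulosa cell division, -2.65, 0.37 and -0.16. The activin-binding protein FST had -1.89, -1.65 and 0.00. GJA1, the main gap junction protein of granulosa cells, lay below 0 in every pair, with -1.76, at least 3.70-fold lower in pair 2, and -0.73 (mean -1.46 ± 0.63, SD, n = 3 pairs), and limma's adjusted p was 0.793. Its second probe had -0.70. The subunit genes INHA and INHBA had means of -0.18 ± 1.05 and -1.10 ± 1.14, and the INHBA arrays of pair 1 read -0.33 and -4.38. LHCGR, the LH receptor, was at least 2.80-fold lower in pair 1 and had -0.40 and 0.07 in pairs 2 and 3. STAR had a mean of -0.42 ± 0.33 and SERPINE2 -0.43 ± 1.04. Signals of the young cows lay near the maximum on 5 of 6 arrays for INHA, INHBA and SERPINE2 and 3 of 6 for GJA1, which limits their ratios. FSHR, the FSH receptor, stood at 0.01 ± 0.20, IGF1R at 0.06 ± 0.55 and IGFBP2 at 0.00 ± 0.06. Signals of the aged cows were above the negative controls on 5 of 6 arrays for CYP11A1, 4 of 6 for HSD3B1 and STAR, and 3 of 6 for LHCGR. HSD3B1, STAR and LHCGR each missed 1 array in pair 2, where bright negative controls raised the threshold of the aged cow on 1 array. No probe of IGF1, IGFBP5, ESR2 or FOXL2 passed the filter.

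Of the 29 gene lists, 4 passed camera with the preset correlation and 0 with an estimated one. Genes of the cell cycle had a mean log2 ratio over 42 measured genes of -0.48 ± 0.79 (SD, n = 3 pairs) and camera adjusted p = 5.52e-06. The adjusted p was 0.778 with an estimated correlation. Of the 42, 36 had lower mean values, 4 at an unadjusted p under 0.05. These were CDK1, which drives mitosis, at -0.68, CCNE2 at -0.44, GMNN, which limits replication to once per cycle, at -0.86, and CENPF at -1.02. CDK1 and CCNE2 were above the negative controls in aged cows on 3 of 6 arrays, and on none of pair 1, where they were at least 1.56-fold and 1.37-fold lower. They also missed 1 array of pair 2, the pair with the raised threshold. The list means of pairs 1 to 3 were -1.35, 0.21 and -0.29. In log2 intensities per cow, centred per gene on the 6 cows, the aged cow of pair 1 stood apart at -1.12. The aged cows of pairs 2 and 3 had 0.35 and 0.06, and the young cows of pairs 1 to 3 had 0.22, 0.13 and 0.36.

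Genes of the unfolded protein response and chaperones had a mean of -0.32 ± 0.24 (SD, n = 3 pairs) over 26 measured genes, 19 of them lower, with means of -0.56, -0.33 and -0.07 in the pairs. The camera adjusted p was 0.000645, and 0.778 with an estimated correlation. Its members with the smallest p were HSPA5, the main chaperone of the endoplasmic reticulum, at -1.35, MANF at -1.16, PDIA6 at -0.49 and EIF2AK3 at -0.33, with 6 members lower at an unadjusted p under 0.05. With the aged cow in Cy5, PDIA6 read -0.31, -0.06 and 0.35 and EIF2AK3 0.02, -0.06 and -0.07, against -0.61, -1.05 and -1.29 and -0.73, -0.63 and -0.48 in the other orientation. Signals of PDIA6 lay near the maximum on 5 of 6 arrays in young cows. Genes of DNA damage response and repair had a mean of -0.19 ± 0.16 over 31 genes, 20 of them lower, and means of -0.36, -0.03 and -0.16 in the pairs. Their camera adjusted p was 0.0145, and 0.778 with an estimated correlation. RAD50 at -0.71 and MRE11 at -0.67, partners in 1 complex, led this list with TP53BP1 at -0.41 and CHEK1 at -0.91, and 5 members were lower at an unadjusted p under 0.05.

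Ribosomal protein genes had a mean log2 ratio of 0.39 ± 0.57 (SD, n = 3 pairs) over 62 genes, 57 of them higher, and camera adjusted p = 9.78e-12. The adjusted p was 0.778 with an estimated correlation. The means of the pairs were 1.05, -0.02 and 0.14. In centred log2 intensities per cow, the aged and young cow of pair 1 stood at 0.60 and -0.45. Those of pair 2 had 0.03 and 0.04, and those of pair 3 -0.04 and -0.18. Besides RPL36, the smallest p values belonged to RPS29 at 0.66, RPS15 at 0.71 and RPL27 at 0.59, and 9 members were higher at an unadjusted p under 0.05. On the 3 arrays with the young cow in Cy5, the means of RPS29 and RPL27 were -0.013 and -0.032. Signals of RPS29, RPS15 and RPL27 lay near the maximum on 5 of 6 arrays in aged and 3 of 6 in young cows, which limits their ratios. In total 33 of the 62 genes had such a signal, and without those probes the mean of the cytosolic ribosomal proteins was 0.37, with camera adjusted p = 1.74e-07. Adjusted over the list alone, limma called 1 ribosomal gene, RPL36, whose spread is limited as said, and 0 genes of the cell cycle, chaperone and DNA repair lists. Over all genes tested it called 0 in each of the 4 lists. Without pair 1, 0 of the 29 lists passed, and the means of the cell cycle, chaperone, DNA repair and ribosomal lists were -0.041, -0.20, -0.099 and 0.063. The estimated correlation was 0.528 for the cell cycle, 0.568 for ribosomal, 0.113 for chaperone and -0.0163 for DNA repair genes. That test also has 2 residual degrees of freedom. The DNA repair list, whose estimate lay below the preset 0.01, did not lose its call through correlation. For the other lists the effects of correlation and of degrees of freedom were not separated.

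**Figure D2:**
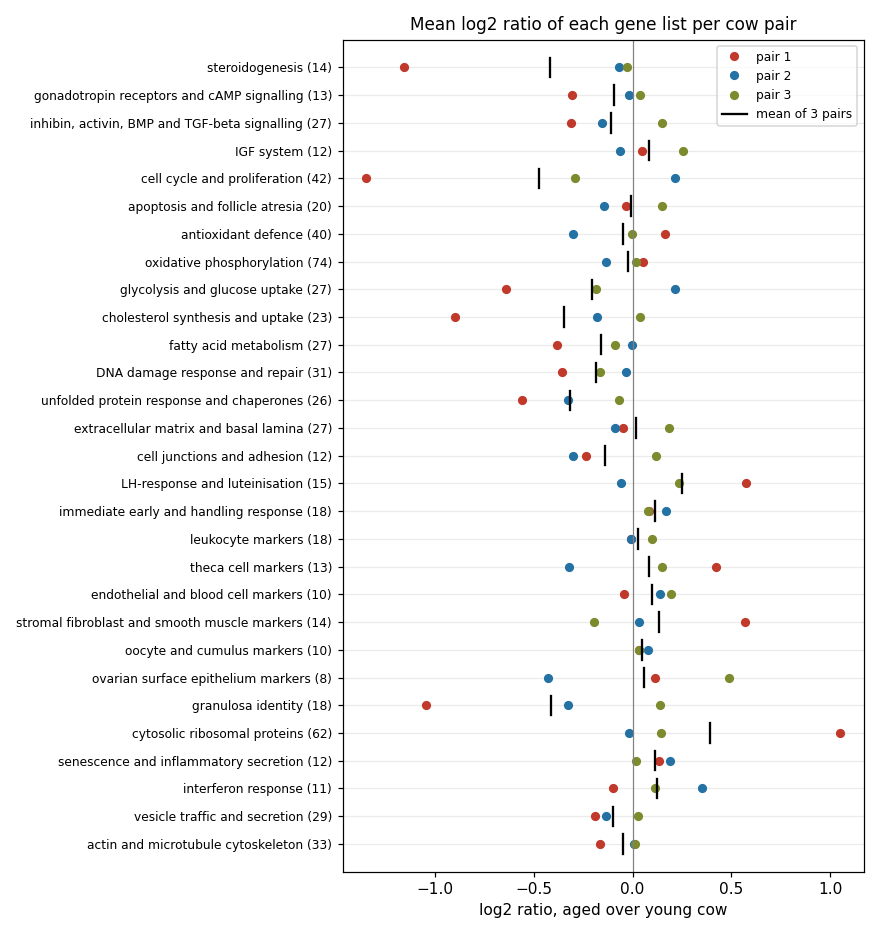
Mean log2 ratio of aged over young cow (x axis) for each of 29 gene lists (y axis, number of measured genes in brackets), 1 point per cow pair and a black bar at the mean of 3 pairs. Pair 1 holds the lowest value of the cell cycle list, -1.35, and the highest of the ribosomal list, 1.05.

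Other groups did not pass. Steroidogenesis genes had a mean of -0.42 ± 0.64 (SD, n = 3 pairs), 12 of 14 lower, and camera adjusted p = 0.14. Without pair 1 the mean was -0.050. Granulosa identity genes had -0.41 ± 0.60, 13 of 18 lower, and -0.096 without pair 1. Among them CDH2, an adhesion protein, had 1.04 ± 0.34, while its other probes had 0.54 and -0.09. Cholesterol synthesis genes had -0.35 ± 0.49, 16 of 23 lower, with IDI1 at -1.20 and MSMO1 at -1.22. Their camera adjusted p was 0.096, 0.0385 with the pair as a block and 0.778 with an estimated correlation, and their mean was -0.073 without pair 1. Glycolysis genes had a mean of -0.20 ± 0.43, 18 of 27 lower, with PGK1 at -0.77. Without pair 1 that mean was 0.014, and in pair 2 it was 0.21. Antioxidant genes went both ways, 17 higher and 23 lower, with PRDX1 at -0.78 and SOD1 at -0.68 against GPX3 at 1.32. The list of activin, BMP and TGF-beta genes had a mean of -0.11 ± 0.23 but a median above 0, 15 higher and 12 lower, with ID2 at -1.22 ± 0.38 and SMAD6 at 0.79, and without pair 1 the mean was -0.0046. Oxidative phosphorylation genes stood at -0.02 ± 0.10, and at -0.058 without pair 1, 32 higher and 42 lower. Among them NDUFS5 had 0.72, ATP5PF -0.76 and UQCRB -0.50, with 3 members higher and 4 lower at limma's unadjusted p under 0.05. LH-response genes stood at 0.25 ± 0.32, 9 higher and 6 lower, with VNN2 at 1.82. Their mean was 0.089 without pair 1, and 0.063 without VNN1, the member with a signal near the maximum. TNFAIP6 was at least 22.7-fold lower in pair 1, with -0.23 and -0.65 in pairs 2 and 3. In these 8 groups limma called 0 genes over all genes tested and 0 adjusted over the list alone, with 18 genes at an unadjusted p under 0.05.

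Measured markers of other cell types were near 0 on average, but many had no kept probe. Measured were 18 of 40 leukocyte, 10 of 29 endothelial and blood cell and 13 of 23 theca markers. The same held for 8 of 13 surface epithelium, 10 of 24 oocyte and cumulus and 14 of 25 stromal markers. Such means do not show that the cell shares were equal. Leukocyte markers had a mean of 0.03 ± 0.06 (SD, n = 3 pairs), endothelial and blood cell markers 0.10 ± 0.13, theca markers 0.08 ± 0.38 with a median below 0, surface epithelium markers 0.06 ± 0.46 and oocyte and cumulus markers 0.05 ± 0.03. Stromal and smooth muscle markers had 0.14 ± 0.39, with 0.57 in pair 1, the pair with the lowest cell cycle and steroidogenesis values. Without that pair the theca and stromal means were -0.088 and -0.081. In pair 1 the stromal members MYH11 and PDGFRA had 3.73 and 1.86, while LUM had -0.77. CNN1 had 0.56 there, with neither cow above the negative controls. Of the 14 stromal members 8 were higher and 6 lower over the pairs, and limma adjusted over the list alone called 1, MYL9. Over all genes tested it called 0, with 1 at an unadjusted p under 0.05.

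The 2 arrays of a pair gave more alike ratios than arrays of different pairs. Across genes, which are not independent replicates, the aged/young log2 ratios of the dye-swapped arrays correlated with r = 0.739, 0.779 and 0.506 in pairs 1 to 3. Between pairs r was -0.222 for pairs 1 and 2, 0.0407 for pairs 1 and 3 and 0.224 for pairs 2 and 3. On both arrays 656 genes differed at least 2-fold in pair 1, 603 in pair 2 and 99 in pair 3. Pairs 1 and 2 shared 19 of them in the same direction, where 20.47 would be shared by independent lists, and 97 in opposite directions, where 20.38 would. Pairs 1 and 3 shared 23 in the same direction, with 3.265 expected, and 13 in opposite directions, with 3.442 expected. For pairs 2 and 3 the numbers were 9 with 3.031 expected and 7 with 3.134 expected.

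**Figure D3:**
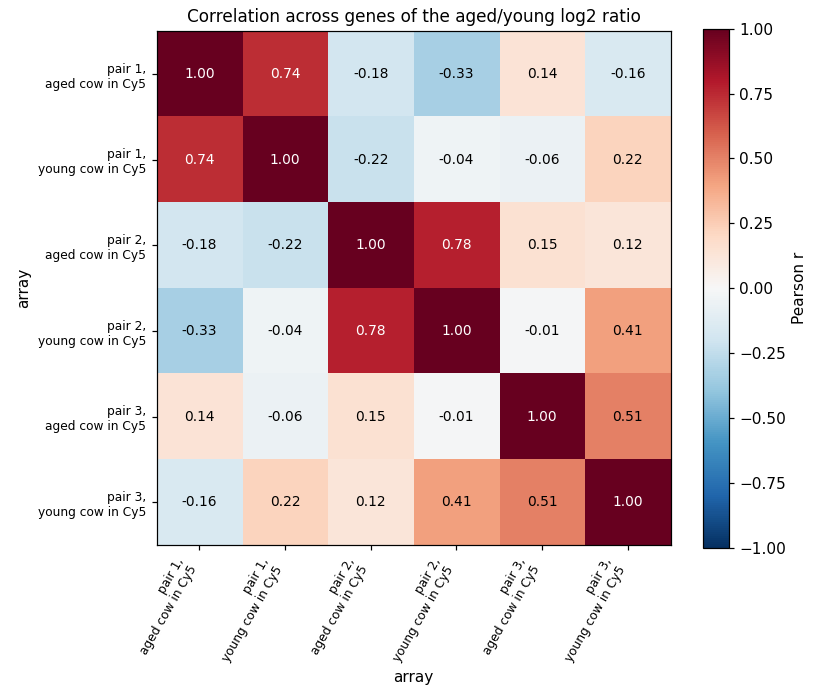
Pearson correlation across genes of the aged/young log2 ratio between each of the 6 arrays (both axes), coloured from -1 in blue to 1 in red. The 2 arrays of a pair correlate at 0.51 or more, and arrays of different pairs at 0.41 or less.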

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

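The test of slide and dye was planned, and the tests by turning pairs were chosen after the results were seen. In 2206 of 9683 genes the aged/young ratio differed between the slide with the aged cow in Cy5 and the slide with the young cow in Cy5, by limma's adjusted p on 6 arrays with the pair as a block. Dye and slide cannot be told apart here, since each slide holds 1 orientation. Of these genes 48 had a signal near the maximum. BLVRB, with no such signal, read 0.09, 0.05 and 0.24 with the aged cow in Cy5 and 1.01, 1.02 and 0.98 with the young cow in Cy5, while SMAD6 read 0.15, -0.17 and -1.03 in the first orientation and 2.27, 2.12 and 1.41 in the second.

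Turning the direction of 1 pair at a time gives 4 splits of the samples, the real one included, too few for a share under 0.05. The real split gave 0 genes past limma's adjusted p and the highest of the others 0, so that 4 of the 4 splits were as large. At an unadjusted p under 0.05 the real split gave 597 genes and the others 964, 470 and 287. With a 2-fold change added, the real split gave 29 genes and the highest other 117, and 3 splits were as large. For gene lists the real split gave 4 and the highest other 5, and 2 splits were as large. The split with 117 genes is that with pair 1 turned, which points to a structure of the samples in which pairs 1 and 2 differ in opposite directions.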

How the results depend on the processing

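The filter from the median of the negative controls, the fit without the array with the brightest negative controls, the fit without probes near the maximum and the count at unadjusted p alone were chosen after the data were seen. Under the settings tried limma called 0 genes past the adjusted p, except 9 with the 6 arrays treated as independent, which counts technical dye swaps as replicates. Those were CRISPLD2, TP53BP2, HAT1, MYL9, H2AZ1, POLR1D, ID2, TFDP1 and SPCS3. In the fit without the array in doubt 0 genes and 4 lists passed, with 456 genes at an unadjusted p under 0.05. In the unpaired fit, with no block, 0 genes passed. Where the cause is not named, the cause was not tested. Dim signals limit the values of genes near the negative controls.

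The 29 genes at unadjusted p and 2-fold became 50 with the stricter filter, 71 with the authors' processed values, 19 with the mean of a gene's probes, 56 with the dye term and the pair as a block, 59 with 6 independent arrays, 192 on the slide with the young cow in Cy5 and 19 with unpaired cows. Without each pair in turn they ranged from 67 to 106. The 597 genes at unadjusted p became 1002 without a filter and 127 with the stricter filter, where more and fewer genes were tested, 908 with the block, 1260 with independent arrays, 1261 on the slide with the young cow in Cy5 and 231 with unpaired cows. The 4 lists became 7 with the stricter filter, 2 on the slide with the young cow in Cy5, 0 with an estimated correlation and 0 to 7 without each pair, with 0 lacking pair 1. The mean correlation of dye-swapped arrays fell to 0.362 in the authors' processed values.

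With an estimated correlation, the means of -0.48 for the cell cycle, -0.19 for DNA repair, -0.32 for chaperones and 0.39 for ribosomal genes no longer passed, at an adjusted p of 0.778 each. DNA repair also lost its call at -0.092 with the stricter filter, -0.15 with the authors' values, -0.14 on the slide with the aged cow in Cy5 and -0.23 on the other, where chaperones lost theirs at -0.31. Without each pair in turn the cell cycle mean ranged from -0.82 to -0.041, DNA repair from -0.26 to -0.099, chaperones from -0.44 to -0.20 and ribosomal genes from 0.063 to 0.60. All 4 lost their call without pair 1, and DNA repair without pair 3 too.

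Log2 values of uncalled lists and of genes that changed sign are given by setting. With the authors' processed values, apoptosis had 0.0090, extracellular matrix -0.00042, leukocyte markers -0.017, surface epithelium -0.017, FSHR -0.026, AMH -0.16 and IGF1R -0.047. With median centring, apoptosis had 0.068, antioxidant defence 0.038, oxidative phosphorylation 0.081, cytoskeleton 0.058 and INHA 0.011. With quantile normalization, extracellular matrix had -0.021, surface epithelium -0.046, FSHR -0.0018, AMH -0.0062 and IGF1R -0.050. With local background subtracted, FSHR had -0.021. With no background correction, FSHR had -0.030. With the filter from the median of the negative controls, apoptosis had 0.0047. With an offset of 16, apoptosis had 0.0049. Without probes near the maximum, apoptosis had 0.065, and 0 genes and 4 lists passed. Without the array in doubt, apoptosis had 0.016, AMH -0.20 and SERPINE2 0.033. With the mean of a gene's probes, extracellular matrix had -0.0060. With the stricter filter, gonadotropin signalling had 0.0047 and cytoskeleton 0.0084. On the slide with the aged cow in Cy5, apoptosis had 0.054, cell junctions 0.011, oocyte markers -0.011, INHA 0.28, INHBA 0.35, AMH -0.37, IGF1R -0.047, SERPINE2 0.21, TM7SF2 -0.22, OXT -0.22, TXN2 -0.19 and SMAD6 -0.35. On the slide with the young cow in Cy5, oxidative phosphorylation had 0.050, extracellular matrix -0.098, leukocyte markers -0.0029, IGFBP2 -0.10, RPS29 -0.013 and RPL27 -0.032.

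Without each pair in turn, list means that changed sign ranged from -0.16 to 0.0080 for gonadotropin signalling, -0.0068 to 0.15 for the IGF system, -0.088 to 0.058 for apoptosis, -0.15 to 0.081 for antioxidant defence, -0.058 to 0.034 for oxidative phosphorylation, -0.41 to 0.014 for glycolysis, -0.067 to 0.069 for extracellular matrix, -0.0086 to 0.045 for leukocyte markers, -0.088 to 0.28 for theca markers, -0.081 to 0.30 for stromal markers, -0.16 to 0.30 for surface epithelium and -0.080 to 0.010 for cytoskeleton. Genes that did so ranged from -0.095 to 0.11 for FSHR, -2.41 to 0.73 for CYP11A1, -1.84 to 0.028 for HSD3B1, -0.69 to 0.36 for INHA, -1.01 to 1.05 for AMH, -0.25 to 0.24 for IGF1R, -0.026 to 0.029 for IGFBP2, -1.41 to 0.11 for CCND2 and -0.91 to 0.12 for SERPINE2. Lists that did not pass at first passed in 15 cases. Cholesterol genes passed with median centring at -0.26, the stricter filter at -0.58, the block at -0.35, independent arrays at -0.35, the slide with the aged cow in Cy5 at -0.34, without pair 2 at -0.43 and without pair 3 at -0.54. Granulosa identity passed with the stricter filter at -0.62, with unpaired cows at -0.41 and without pair 3 at -0.69. Glycolysis passed with the stricter filter at -0.34 and without pair 2 at -0.41, and steroidogenesis without pair 2 at -0.59. Activin, BMP and TGF-beta genes passed with the stricter filter at -0.37, and interferon response with the filter from the median of the negative controls at 0.14. Without pair 1 none of these lists passed.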

Other observations

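All tests in this part were chosen after the results were seen, and genes named here were chosen after their values were seen. In pair 1 the genes named next were lower in the aged cow. FADS2, a fatty acid desaturase, had a log2 ratio of -3.78, INHBB, the inhibin beta B subunit, -3.42, and RRM2, a subunit of ribonucleotide reductase, -3.19. LRP8, a lipoprotein receptor, was at least 13.6-fold lower, with signals of the young cow near the maximum on both arrays. TNFAIP6, a matrix protein of the expanding cumulus, was at least 22.7-fold lower, with no signal of the aged cow above the negative controls on either array. Higher in the aged cow were MAN1A1 at 5.09, MXRA8 at 4.48, MYH11, a smooth muscle marker, at 3.73, NRP1 at 3.25 and SELENOP at 3.45. ANGPT2 was at least 29.8-fold higher there. VNN1, a pantetheinase, was higher there, with log2 ratios of 9.14 and 5.90 on the 2 arrays and a mean of 7.52, which is no bound. Its signals lay near the maximum in the aged cow on both, and were above the negative controls in the young cow on 1. In pair 2 VNN1 was lower in the aged cow, which was above the negative controls on 0 of 2 arrays, while the young cow was on both. In pair 3 VNN1 was at least 6.39-fold higher in the aged cow, and GATM in pair 1 at least 27.1-fold higher.

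In pair 2 the genes at opposite ends included H2AX, a histone of DNA break signalling, at 2.41 against -2.40 in pair 1, and NAV1 at 2.56 against -2.58. IDH3A, of the citric acid cycle, went the same way in both, with -3.26 and -2.22, and stood at -0.08 in pair 3. In pair 3 the aged cow had less LUM, a collagen-binding proteoglycan, at -4.07, and more of the epithelial genes KRT19 at 1.88 and PPL at 2.41, with FN1 at 2.40. The young cow of pair 3 was above the negative controls for KRT19 on 1 of its 2 arrays.

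The first pattern weighed is the lower steroidogenic and cell cycle genes of the aged cow in pair 1. Both list means lay at or below -1.08 on both arrays, which carry opposite dyes. A slide effect would also reach pairs 2 and 3, on the same slides. There the cell cycle means were 0.21 and -0.29 and the steroidogenesis means -0.07 and -0.03. These values argue against a dye or slide effect as the whole cause. A smaller share of granulosa cells could raise the markers of all other types alike, and their means in pair 1 were 0.57 for stromal, 0.42 for theca, -0.01 for leukocyte and -0.046 for endothelial markers, but stromal exceeded leukocyte markers by 0.58 with an SE over genes of 0.33, which leaves it open. A response to an LH surge would be expected to raise LH-response genes, whose mean in pair 1 was 0.58 with an SE of 0.65, and 0.08 without VNN1, so it stays open. A first form of that test, on CYP11A1 at -4.52 and TNFAIP6, at least 22.7-fold lower, alone, would have argued against the surge, but these were picked for their values and the whole list replaced them. Age and parity stay open and untested, as does the method of collection, which the labels do not give per cow.

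Opposite changes in pairs 1 and 2 were weighed against a dye or slide effect and against exchanged labels. Averaging both orientations removes an additive dye effect that is the same on both slides, but a slide effect can remain. The correlation of the 2 averaged pairs was -0.222, but that value also showed the pattern. Between arrays of the same orientation, where a dye or slide effect would raise the correlation, r was -0.185 and -0.0412. These values argue against it as the whole cause. Exchange of the labels of the aged and young cow in pair 1 could make that pair resemble the others once turned, and it then correlated with pair 2 but at -0.0407 with pair 3, while unturned it shared 23 genes with pair 3 in the same direction and 13 in opposite ones, which leaves this open. Differences between single cows of an age group remain another open explanation, as 1 cow of each group enters each pair. The collection and storage of the cells, which the labels do not give per cow, stay open and untested too.

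The higher ribosomal protein genes of the aged cow in pair 1 were weighed against 2 explanations. A dye or slide effect is argued against as the whole cause, with list means of 1.32 and 0.76 on its arrays, and of 1.09 and 1.16 without the 33 genes with a signal near the maximum. A bias towards short abundant transcripts could raise genes of oxidative phosphorylation too, and these had a mean of 0.051 with an SE over genes of 0.06 in pair 1, against 1.05 with an SE of 0.06 for ribosomal genes. Transcript lengths were not measured here, so that comparison rests on general knowledge of both gene groups. Age and parity stay open and untested, and the list means were -0.02 and 0.14 in pairs 2 and 3.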
